A study of Mus musculus with 20 samples.

How the data were processed

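Expression was measured in total RNA from a murine B16 Bcr-Abl+ line transfected with a void plasmid or with p65/RelA constructs: wild type (WT), the non-cleavable D361E form, residues 1 to 361 (N-fragment), residues 362 to 549 (C-fragment) and both fragments together (N+C). Samples titled "Blanck" were read as void plasmid. N+C had 5 arrays and every other group 3, 20 arrays in 6 groups, and no sample was left out. The labels do not state how the replicates were made. No paired analysis was possible because the titles carry only running numbers.

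The authors hybridized Cy3-labelled RNA to 1-colour Agilent arrays with 44397 features, and the deposited scanner files hold intensity values written by Agilent Feature Extraction 10.7.3.1. Per the file headers the 20 arrays sat on 5 slides of 4 and were scanned on 1 day. The processed signal in them is background-subtracted, and the deposited series table was checked to equal it on every feature of every array, so no scaling between arrays had been applied. Of the 43020 non-control spots 51.1 to 57.9% (21982 to 24897) were well above background per array, which sets how many genes can be compared. Probes were named through their accession in a RefSeq gene table: 28663 of 39429 non-control probes (72.7%) received a symbol and 10766 did not.

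All values were computed with limma 3.58.1 in R 4.3.3. Intensities were put on the log2 scale and the array's 75th percentile over non-control probes was subtracted, a percentile that differed up to 1.448-fold between arrays. Spots flagged as outliers, 98 to 285 per array, were left out, and no spot was saturated. Probes well above background on at least 3 of the 20 arrays were kept (23432), and each symbol was represented by its brightest probe, giving 18738 genes, of which 13823 had symbols and 4915 had none. A linear model with all 20 arrays and the 6 groups was fitted per gene (residual df 14, prior df 1.44), with moderated statistics and Benjamini-Hochberg adjustment within each comparison, and genes with an adjusted p under 0.05 were called changed.

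The 10 comparisons were these: each of the 5 constructs against void, the other 4 against WT, and N+C beyond the sum of both fragments, which is N+C minus N-fragment minus C-fragment plus void. A change of equal size in N+C and in both fragments therefore enters that last comparison with its sign turned. Where no array of a group was above background, the fold is given as "at least", computed against the background floor of those arrays, with the adjusted p of the unbounded difference. Because N+C arrays share the fit, their spread also enters the error of comparisons without them.

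Genes named in the text followed a rule set before the data were examined: Rela, then per comparison the 10 largest rises and 10 largest falls among called genes with symbols whose groups did not overlap, taken from the top, and up to 2 called members per direction of each gene list. The tests, the filter, the comparisons and 21 gene lists with 410 members were also chosen beforehand. Of the members 400 had a symbol on the array and 325 passed the filter (measured). The lists cover NF-kB family and feedback genes, NF-kB inflammatory targets, anti-apoptotic and pro-apoptotic genes, MHC class I presentation, interferon-stimulated genes and p53 targets. They also cover melanocyte, haematopoietic and B-lymphoid, macrophage, fibroblast and epithelial markers, cell cycle genes, the unfolded protein and integrated stress response, NRF2 targets, glycolysis and hypoxia genes, cholesterol synthesis, immediate early genes, mesenchymal and TGF-beta response genes, STAT5 targets and ribosomal protein genes. Lists were tested with camera at a preset correlation of 0.01 on the 18671 genes without a missing value, and again with an estimated correlation and with fry. Some genes that the rule names are not used here. Background clauses on genes are general knowledge and were not tested.

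Profiles against void share the void arrays, so their correlation and covariance were set beside 100 simulations. Each shuffled all group labels, void included, over the array residuals. Overlaps were set beside the product of both counts over the number of genes. With 3 void arrays, too few for 2 sets of 2, the shared part was not removed.

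Tested on simulated data, the fit recovered 44.8, 58.2 and 84.8% of genes changed by 0.5, 1 and 2 log2 units for WT against void, with 0.79% of calls false. For N+C against void it recovered 46.3, 71.6 and 84.8%, with 4.93% false, and beyond the sum 19.4, 61.2 and 86.4%, with 4.31% false. A list shifted by 0.5 was called (adjusted p = 1.29e-19) with 0 of 20 others, but genes were simulated independently.

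Alternatives chosen before the data were examined were quantile normalization, normexp background correction (offset 50) with quantile normalization, the series table without scaling, no filter and a filter on all arrays, the mean of a gene's probes, only the groups of the comparison, trend and robust moderation, array weights, slide as a block, a 2-fold minimum and leaving out each array. The files hold no mean signal, so normexp used the median spot and background signals. Fits of N+C without arrays 4 and 5 and without arrays 1 to 3 were added after seeing the data. Group labels were also divided in every other way among the arrays of a comparison, or drawn 100 times for the beyond-the-sum comparison. The strain label names C3H eOuJ mice although the line is called B16, and this was not resolved here.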

Results

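Genes of the melanocyte lineage were expressed in all 20 arrays, whichever construct the cells had received. All 16 melanocyte markers were above background on every array. Of 20 haematopoietic and B-lymphoid markers 8 were measured, and 5 were above background on all 20 arrays. Rela, the gene of p65 itself, was above background on every array, though where its probe lies relative to the fragments was not worked out here. Against void plasmid Rela rose with the N-fragment (1.28-fold, log2 0.36 ± 0.07, adjusted p = 0.00089) and was not called with wild-type p65 (log2 0.07 ± 0.07, adjusted p = 0.571), D361E (log2 0.08 ± 0.07, adjusted p = 0.521), the C-fragment (log2 0.08 ± 0.07, adjusted p = 0.474) or both fragments together (log2 0.18 ± 0.06, adjusted p = 0.0512). Values after ± are standard errors of the log2 difference, and p-values measure only the spread between these samples, since the labels do not say whether they are separate cultures.

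Against void plasmid 5829 genes changed with the N-fragment, 4601 with both fragments together (N+C, 5 arrays where other groups had 3), 2527 with D361E, 2460 with the C-fragment and 1759 with wild-type p65 (WT). Their order depended on processing, since unscaled values gave 7678 for WT and 7444 for the N-fragment, and fits with only the groups compared gave 2023 for N+C, 2561 for the C-fragment, 1532 for WT and 1451 for D361E. Targets of p53 were lower than with void plasmid for each of the 5 constructs. The family and feedback genes of NF-kB were higher with WT and with non-cleavable D361E, and were lower with the C-fragment than with WT. With the N-fragment these genes had a mean level of -0.93, beside -0.92 with WT and -1.42 with void, but their list call was lost with an estimated correlation. With N+C they were below WT too, but not called with an estimated correlation (adjusted p = 0.0753). Of the 21 gene lists the camera test with the preset gene-gene correlation called 5 to 12 per comparison, but with other divisions of the same arrays it still called a median of 3 to 6. The fry test, which asks only whether a list changed at all, called 8 to 14. List calls below are those of camera. With the correlation estimated from the data the median of other divisions was 0, and the highest was 3 for N+C against void (real 4), 2 for N+C against WT (real 0) and 0 elsewhere. Divisions of 3 and 3 arrays keep part of the real difference and are no clean null. Both p-values are printed for called lists. The 5 N+C arrays lay in 2 sets, described with the first N+C comparison.

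**Figure D1:**
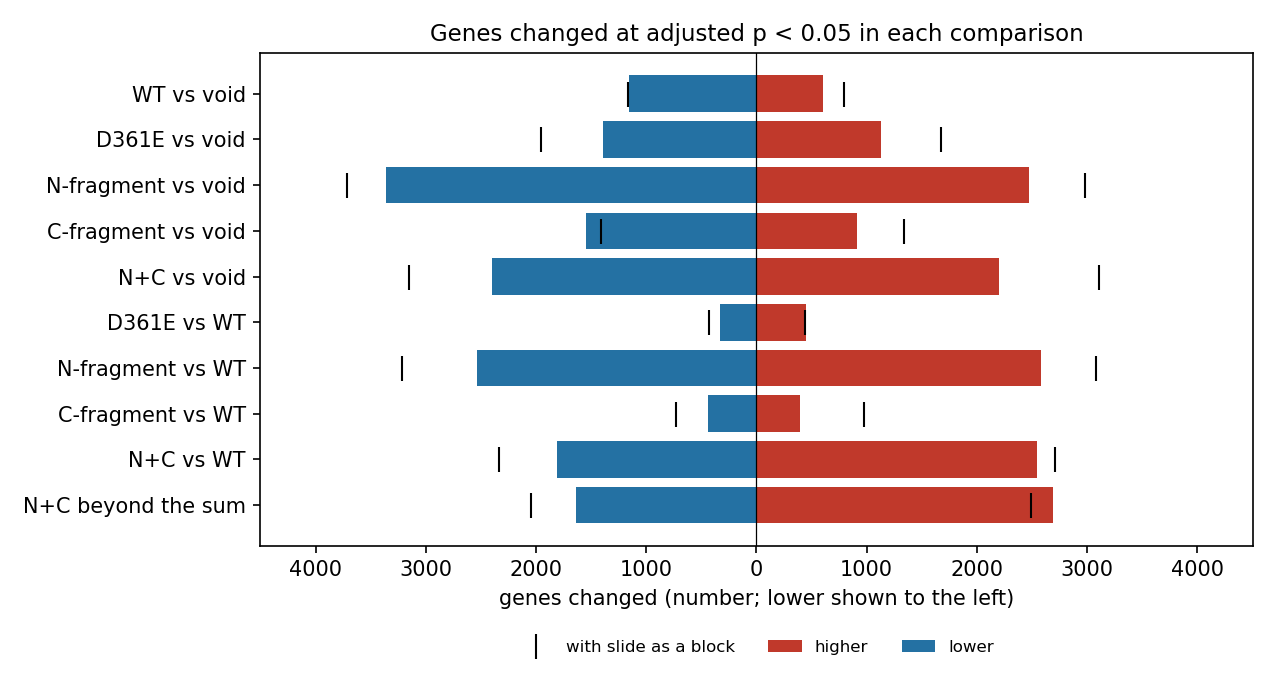
Genes higher and lower in each comparison at an adjusted p under 0.05; ticks mark the numbers with slide as a block.

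**Figure D2:**
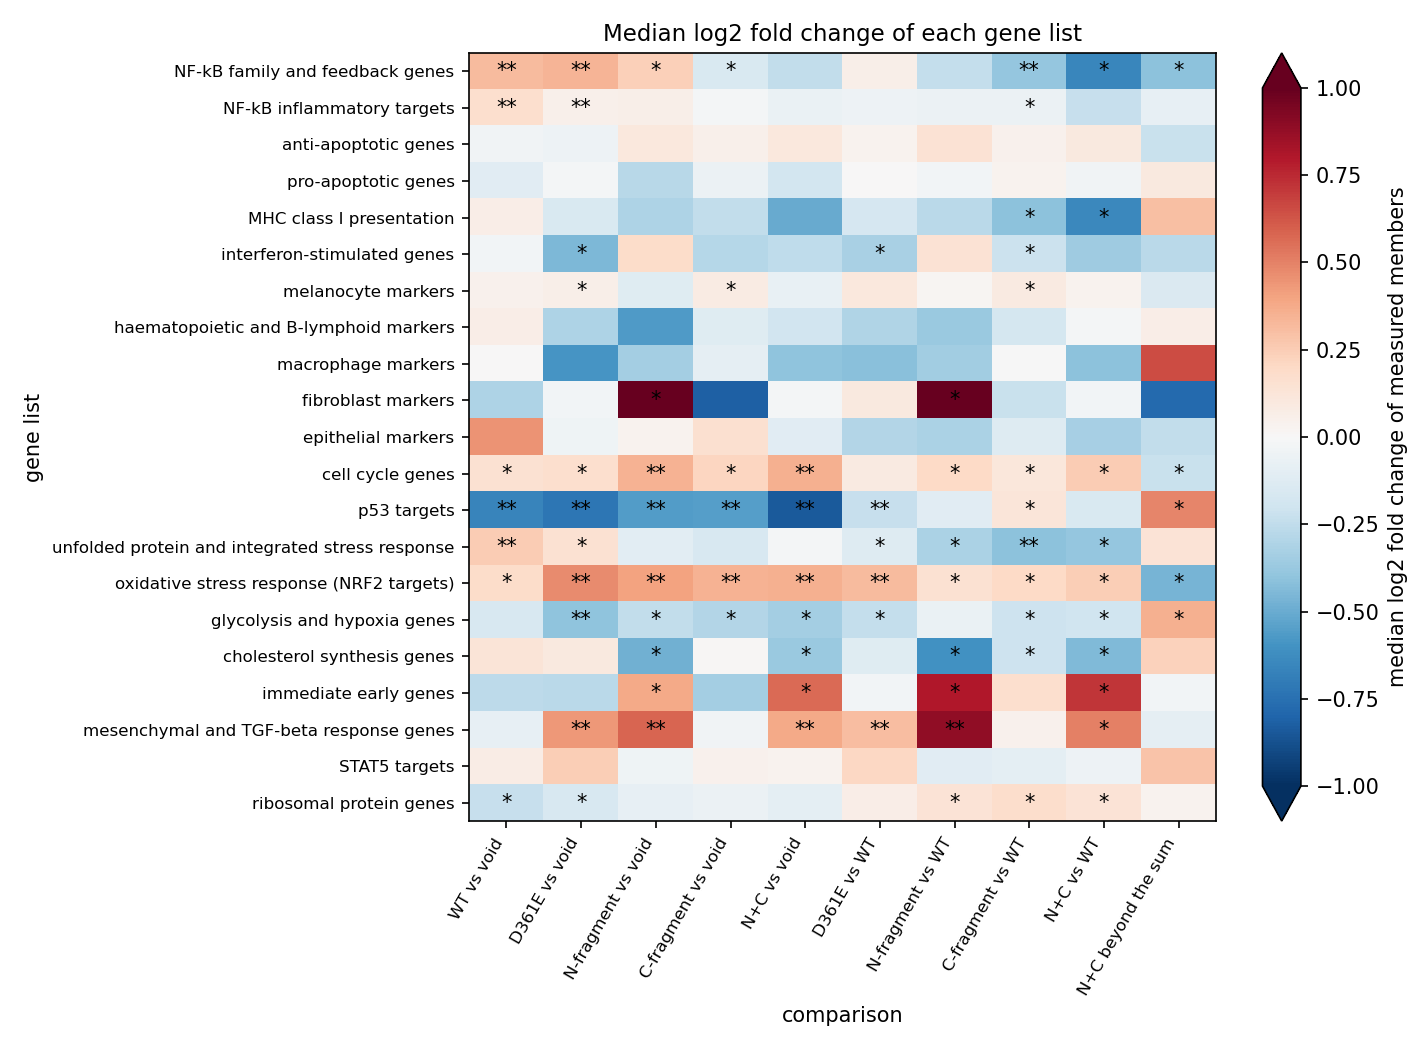
Median log2 difference of the measured members of each gene list in each comparison; 1 star marks lists called with the preset correlation and 2 stars those also called with an estimated correlation.

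With wild-type p65, NF-kB feedback genes, Cxcl1 and Cxcl10 were higher than with void plasmid and p53 targets were lower. Tnfaip3, which encodes the A20 feedback inhibitor of NF-kB, rose (6.09-fold, log2 2.61 ± 0.15, adjusted p = 2.68e-08), as did the nuclear IkB gene Bcl3 (log2 1.35 ± 0.16). The neutrophil-attracting chemokine Cxcl1 was at least 6.06-fold higher (adjusted p = 5.51e-05), and the interferon-inducible chemokine Cxcl10 rose (log2 1.60 ± 0.08). Higher too were Capn6, a calpain without protease activity (at least 23.5-fold higher, adjusted p = 1.32e-12), Rnf113a2, a ring finger gene (at least 10.6-fold higher, adjusted p = 1.69e-06), and the quinone reductase Nqo1 (at least 5.42-fold higher, adjusted p = 2.08e-08). Lower were Ldhd, a mitochondrial D-lactate dehydrogenase (at least 34.9-fold lower, adjusted p = 0.000609), the asparaginase Aspg (log2 -6.40 ± 0.52, above background on 1 of 3 WT arrays) and the actin-binding Tagln2 (log2 -4.85 ± 1.05, above background on 2 of 3 WT arrays). Changed genes numbered 1759 of 18738, 604 higher and 1155 lower, 285 of them at least 2-fold (n = 3 and 3).

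For the NF-kB family and feedback genes 5 of 19 measured members rose, 0 fell and 14 were not called (adjusted p = 3.9e-07, adjusted p = 0.0467 with an estimated correlation). NF-kB inflammatory targets were higher (4 of 16 rose, 0 fell, adjusted p = 0.00992, adjusted p = 0.047 with an estimated correlation). Ccl2 and Cxcl1, absent with void, could only rise. Of the p53 targets 0 of 19 measured members rose, 12 fell and 7 were not called (adjusted p = 6.97e-14, adjusted p = 0.00108 with an estimated correlation). Lowest were the antiproliferative Btg2 (log2 -2.02 ± 0.14) and the autophagy-linked Trp53inp1 (log2 -1.96 ± 0.08). In the unfolded protein and integrated stress response 10 of 24 measured members rose, 0 fell and 14 were not called (adjusted p = 5.43e-11, adjusted p = 0.047 with an estimated correlation). Chac1, which degrades glutathione (log2 1.74 ± 0.21), and the pseudokinase Trib3 (log2 1.73 ± 0.18) led the rise. The preset correlation alone called the cell cycle genes (2 of 29 higher, 1 lower, adjusted p = 0.00457, adjusted p = 0.261 with an estimated correlation). NRF2 targets had that call too (2 of 17 higher, 0 lower, adjusted p = 0.00707, adjusted p = 0.24 with an estimated correlation). Ribosomal protein genes were called likewise (0 of 22 higher, 7 lower, adjusted p = 3.47e-06, adjusted p = 0.261 with an estimated correlation). The ribosomal genes turned with scaling, and Rpl13 (log2 -0.39 ± 0.11) stood at 0.01 on unscaled values. In the list of immediate early genes Egr1 was at least 1.68-fold higher (adjusted p = 0.0206) while Jun fell (log2 -0.94 ± 0.23). In the order given, 9 and 0, 4 and 1, 0 and 12, 15 and 0, 2 and 1, 2 and 0, 0 and 18 members of the called lists were higher and lower when adjusted over the list alone. The 14 other lists were not called by camera (adjusted p from 0.101 to 0.991). Signs differed between median, mean and test for interferon-stimulated genes (median -0.03, mean 0.02, test up) and macrophage markers (median 0.004, mean -0.17, test down). With slide as a block 1956 genes were called, among them 1285 of the 1759 in the same direction. The count was 1000 without void 2, 945 without void 3, 1017 without WT 1, 941 without WT 2, 1135 without WT 3. Without scaling between arrays 7425 genes were higher and 253 lower, with the median of all genes at log2 0.37. Quantile normalization gave 744 higher and 878 lower, and background-corrected quantile values 724 and 816.

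With the non-cleavable D361E form NF-kB feedback and oxidative stress genes were higher than with void plasmid, and p53 targets and glycolysis genes were lower. Tnfaip3 rose (10.5-fold, log2 3.39 ± 0.15, adjusted p = 4.74e-10), and so did Nfkbia, which encodes the inhibitor IkB-alpha (log2 1.54 ± 0.11), and Cxcl10 (log2 2.48 ± 0.08). Nqo1 was at least 15.4-fold higher (adjusted p = 2.72e-10). Lims2, a focal adhesion gene, rose (log2 5.17 ± 0.25), and Rnf113a2 was at least 6.1-fold higher (adjusted p = 3.85e-06). Cyba, which encodes the p22phox subunit of NADPH oxidase, was at least 209-fold lower (adjusted p = 0.0122), Tagln2 fell (log2 -5.46 ± 1.05, above background on 1 of 3 D361E arrays), and the basement membrane collagen Col4a1 was at least 9.42-fold lower (adjusted p = 3.9e-13). Altogether 2527 of 18738 genes changed (n = 3 and 3), 1132 upward and 1395 downward, with 453 changed at least 2-fold.

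Among p53 targets 0 of 19 measured members rose, 13 fell and 6 were not called (adjusted p = 1.26e-17, adjusted p = 0.000305 with an estimated correlation). Plk2, a polo-like kinase, was at least 4.42-fold lower (adjusted p = 3.96e-07) and Btg2 fell (log2 -3.01 ± 0.14). Of the NRF2 targets 8 of 17 measured members rose, 0 fell and 9 were not called (adjusted p = 2.72e-10, adjusted p = 0.00589 with an estimated correlation). The sulfiredoxin gene Srxn1 was among the risers (log2 1.24 ± 0.10). For glycolysis and hypoxia genes 0 of 18 measured members rose, 11 fell and 7 were not called (adjusted p = 3.57e-11, adjusted p = 0.0447 with an estimated correlation). The mitophagy receptor gene Bnip3 (log2 -2.42 ± 0.14) and the peptide hormone gene Adm (log2 -2.40 ± 0.57) were lowest. The NF-kB family list held Tnfaip3 and Nfkbia among its risers: 5 of 19 measured members rose, 0 fell and 14 were not called (adjusted p = 1.69e-06, adjusted p = 0.0447 with an estimated correlation). NF-kB inflammatory targets followed, where 4 of 16 measured members rose, 0 fell and 12 were not called (adjusted p = 0.0182, adjusted p = 0.0447 with an estimated correlation). In the mesenchymal list 5 of 14 measured members rose, 1 fell and 8 were not called (adjusted p = 0.00051, adjusted p = 0.0447 with an estimated correlation). The matricellular Ccn2 (log2 2.39 ± 0.18) and Tgfbi (log2 1.43 ± 0.42) rose and the gelatinase Mmp2 (log2 -0.56 ± 0.14) fell. Called only with the preset correlation were the interferon-stimulated genes (1 of 27 higher, 9 lower, adjusted p = 0.00253, adjusted p = 0.446 with an estimated correlation). Melanocyte markers had that call too (4 of 16 higher, 1 lower, adjusted p = 0.0328, adjusted p = 0.124 with an estimated correlation). Cell cycle genes were called likewise (8 of 29 higher, 1 lower, adjusted p = 0.000153, adjusted p = 0.107 with an estimated correlation). Genes of the unfolded protein and integrated stress response joined them (5 of 24 higher, 4 lower, adjusted p = 0.0363, adjusted p = 0.518 with an estimated correlation). Ribosomal protein genes were a further case (0 of 22 higher, 2 lower, adjusted p = 0.00051, adjusted p = 0.339 with an estimated correlation). In the interferon list the antiviral Rtp4 fell (log2 -1.77 ± 0.32). Id1, a helix-loop-helix inhibitor of differentiation, rose (log2 2.71 ± 0.57). Members of the called lists higher and lower when adjusted over the list alone numbered, in the same order, 0 and 17, 11 and 0, 0 and 13, 6 and 0, 5 and 0, 7 and 1, 3 and 11, 4 and 1, 10 and 2, 6 and 4, 0 and 2. None of the 10 remaining lists was called by camera (adjusted p from 0.078 to 0.856). Median, mean and test differed in sign for anti-apoptotic genes (median -0.05, mean 0.04, test up). In a fit with slide as a block 3631 genes were called, among them 2394 of the 2527 in the same direction. On unscaled values the division was 1852 higher and 554 lower, with the median of all genes at log2 0.12.

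With the N-fragment, cell cycle and mesenchymal genes and NRF2 targets were higher than with void plasmid, and p53 targets were lower. Lims2 (log2 6.60 ± 0.25), Tubb2b (log2 6.07 ± 0.21) and the engulfment receptor Megf10 (log2 5.83 ± 0.48) rose. The olfactory receptor gene Olfr875 was at least 15.5-fold higher (adjusted p = 1.98e-14). The caspase-binding inhibitor gene Birc3 was at least 2.9-fold higher (adjusted p = 0.000278), and the chemokine Ccl5 rose (12.3-fold, log2 3.62 ± 0.17, adjusted p = 2.36e-10). The secreted Dickkopf-family gene Dkk3 was at least 168-fold lower (adjusted p = 9.32e-11). Lgals3, which encodes galectin-3, fell (log2 -6.42 ± 1.00, adjusted p = 0.000132), and Foxr2, a forkhead factor, fell (log2 -6.44 ± 0.54). Changed genes numbered 5829 of 18738, 2472 higher and 3357 lower, 1316 of them at least 2-fold (n = 3 and 3).

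In the cell cycle list 14 of 29 measured members rose, 1 fell and 14 were not called (adjusted p = 1.14e-06, adjusted p = 0.049 with an estimated correlation). Rrm2, a ribonucleotide reductase subunit (log2 0.77 ± 0.09), and the S-phase factor E2f1 (log2 0.74 ± 0.12) rose and the thymidylate synthase Tyms (log2 -0.38 ± 0.08) fell. Within the mesenchymal list 9 of 14 measured members rose, 0 fell and 5 were not called (adjusted p = 1.19e-05, adjusted p = 0.0462 with an estimated correlation). The fibronectin gene Fn1 was among the highest (log2 2.95 ± 0.43). Of the p53 targets 1 of 19 measured members rose, 13 fell and 5 were not called (adjusted p = 3.6e-05, adjusted p = 0.049 with an estimated correlation). Perp, a desmosomal effector of p53, was at least 5.41-fold lower (adjusted p = 5.72e-07). Ei24, the 1 member that rose, stood at log2 1.21 ± 0.10. NRF2 targets split the other way, as 9 of 17 measured members rose, 1 fell and 7 were not called (adjusted p = 3.83e-05, adjusted p = 0.049 with an estimated correlation). Nqo1 was at least 10.4-fold higher (adjusted p = 2e-10). The preset correlation alone called the NF-kB family and feedback genes (8 of 19 higher, 1 lower, adjusted p = 0.0026, adjusted p = 0.154 with an estimated correlation). Fibroblast markers had that call too (3 of 6 higher, 1 lower, adjusted p = 0.0114, adjusted p = 0.154 with an estimated correlation). Glycolysis and hypoxia genes were called likewise (0 of 18 higher, 8 lower, adjusted p = 0.00129, adjusted p = 0.312 with an estimated correlation). Cholesterol synthesis genes joined them (0 of 21 higher, 13 lower, adjusted p = 0.000192, adjusted p = 0.491 with an estimated correlation). Immediate early genes were a further case (7 of 16 higher, 1 lower, adjusted p = 0.00882, adjusted p = 0.23 with an estimated correlation). With probes above background on all arrays the fibroblast list pointed down (adjusted p = 0.369). The 1 NF-kB family gene that fell was Tank (log2 -0.27 ± 0.08), which stood at 0.06 on unscaled values. Col1a1 rose (log2 3.56 ± 0.78) and Fbln1, missing on N-fragment 1 and left out of camera, fell (log2 -1.40 ± 0.16). The anti-apoptotic list was called by fry (adjusted p = 1.11e-06) but not by camera (4 of 10 rose and 1 fell, adjusted p = 0.0595), with the stress gene Gadd45b (log2 1.71 ± 0.11) and Bcl2l1, which encodes Bcl-xL (log2 1.17 ± 0.23), up. Interferon genes moved both ways, with Oasl1 (log2 3.21 ± 0.25) and Ifit1 (log2 1.82 ± 0.14) higher and the antiviral Rsad2 (log2 -1.48 ± 0.49) lower. Adjusted over the list alone, the called lists had, in the order given, 17 and 1, 10 and 0, 1 and 14, 9 and 1, 8 and 1, 4 and 1, 1 and 10, 0 and 14, 7 and 1 members higher and lower. Not called by camera were the 12 other lists (adjusted p from 0.0595 to 0.972). The sign differed between median, mean and test for melanocyte markers (median -0.12, mean -0.06, test up) and STAT5 targets (median -0.04, mean 0.36, test down). Blocking on slide, 6697 genes were called, among them 5362 of the 5829 in the same direction. Left unscaled, the arrays gave 6323 higher and 1121 lower genes, with the median of all genes at log2 0.28.

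With the C-fragment the NF-kB feedback genes Tnfaip3 and Bcl3 were lower than with void plasmid, unlike with WT and D361E, while p53 targets were again lower and oxidative stress genes higher. Tnfaip3 was at least 2.24-fold lower (adjusted p = 6.32e-06), and Bcl3 (log2 -1.43 ± 0.16, adjusted p = 3.23e-05) and Cxcl10 (log2 -1.32 ± 0.08) fell. Nqo1 was at least 7.16-fold higher (adjusted p = 5.1e-09), Rnf113a2 was at least 6.06-fold higher (adjusted p = 8.78e-06), and the tubulin gene Tubb2b (log2 4.75 ± 0.21) and the adhesion molecule Cd99 (log2 3.00 ± 0.40) rose. Cyba was at least 164-fold lower (adjusted p = 0.0136), the secreted phospholipase Pla2g5 was at least 9.75-fold lower (adjusted p = 1.19e-09), and the myelin gene Mbp (log2 -5.43 ± 0.75, above background on 2 of 3 C-fragment arrays) and Aspg (log2 -6.05 ± 0.52, above background on 1 of 3 C-fragment arrays) fell. Altogether 2460 of 18738 genes changed (n = 3 and 3), 915 upward and 1545 downward, with 431 changed at least 2-fold.

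Of the p53 targets 0 of 19 measured members rose, 11 fell and 8 were not called (adjusted p = 2.69e-09, adjusted p = 0.00742 with an estimated correlation). Btg2 (log2 -2.05 ± 0.14) and Trp53inp1 (log2 -1.85 ± 0.08) were again lowest. For NRF2 targets 9 of 17 measured members rose, 0 fell and 8 were not called (adjusted p = 4.64e-07, adjusted p = 0.0262 with an estimated correlation). Gclm, a subunit of the glutathione-making ligase, rose (log2 0.80 ± 0.17). Called only with the preset correlation were the NF-kB family and feedback genes (0 of 19 higher, 3 lower, adjusted p = 0.0128, adjusted p = 0.302 with an estimated correlation). Melanocyte markers had that call too (4 of 16 higher, 0 lower, adjusted p = 0.0227, adjusted p = 0.147 with an estimated correlation). Cell cycle genes were called likewise (5 of 29 higher, 0 lower, adjusted p = 4.76e-06, adjusted p = 0.0995 with an estimated correlation). Glycolysis and hypoxia genes joined them (1 of 18 higher, 8 lower, adjusted p = 1.13e-05, adjusted p = 0.257 with an estimated correlation). In that last list Adm (log2 -2.27 ± 0.57) and Bnip3 (log2 -2.25 ± 0.14) fell, and the carbonic anhydrase Car9 rose (log2 0.66 ± 0.07). The BH3-only genes Bbc3 (log2 -1.09 ± 0.13) and Bcl2l11 (at least 1.72-fold lower, adjusted p = 0.00605) fell in the pro-apoptotic list, where 2 members of 14 rose and 3 fell (adjusted p = 0.529). Pigment genes that rose included Oca2, a melanosomal transporter (log2 0.61 ± 0.11). The receptor gene Pdgfra was at least 1.62-fold lower (adjusted p = 0.00156). In the order given, 0 and 13, 9 and 0, 0 and 4, 5 and 0, 12 and 0, 1 and 10 members of the called lists were higher and lower when adjusted over the list alone. The 15 other lists were not called by camera (adjusted p from 0.0687 to 0.984). Signs differed between median, mean and test for anti-apoptotic genes (median 0.05, mean -0.02, test up), macrophage markers (median -0.09, mean -0.03, test up), cholesterol synthesis genes (median 0.01, mean -0.04, test down) and mesenchymal and TGF-beta response genes (median -0.04, mean 0.000, test up). With slide as a block 2748 genes were called, among them 1842 of the 2460 in the same direction. The count was 1553 without void 2, 1516 without void 3, 1622 without C-fragment 1, 1434 without C-fragment 2, 1542 without C-fragment 3. Without scaling between arrays 2865 genes were higher and 513 lower, with the median of all genes at log2 0.21.

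With both fragments together Egr1, Id1, Ccl5 and cell cycle genes were higher than with void plasmid and p53 targets were lower. The growth-response factor Egr1 was at least 9.51-fold higher (adjusted p = 5.96e-06), Id1 rose (8.57-fold, log2 3.1 ± 0.51, adjusted p = 0.000326) and Ccl5 rose (log2 3.06 ± 0.15). Levels of Id1 were 3.04, 3.07, 2.97 in arrays 1 to 3 and 0.68, 0.97 in arrays 4 and 5, and of Egr1 -1.58, -1.57, -1.47 and -3.99, -3.89. Nqo1 was at least 13.6-fold higher (adjusted p = 8.8e-11), Rnf113a2 was at least 8.34-fold higher (adjusted p = 2.41e-07), the zinc finger gene Zfp521 was at least 19.6-fold higher (adjusted p = 2.47e-07), and Lims2 rose (log2 5.36 ± 0.22). Krba1 was at least 32.7-fold lower (adjusted p = 4.66e-17), and the one-carbon enzyme Mthfd2l was at least 8.47-fold lower (adjusted p = 3.41e-09). Tnfaip3 fell (log2 -1.29 ± 0.13, adjusted p = 4.03e-06, above background on 1 of 5 N+C arrays), as it did with the C-fragment. Changed genes numbered 4601 of 18738, 2204 higher and 2397 lower, 706 of them at least 2-fold (n = 5 and 3).

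For some genes the N+C mean stood for no single array, since arrays 1 to 3 and arrays 4 and 5 lay apart. Between those sets 224 genes had a gap of at least 4-fold, 166 higher and 58 lower in arrays 4 and 5, against at most 18 for the 9 other divisions of the 5 arrays. Armcx2, an armadillo repeat gene, stood at -7.98, -7.73, -7.32 and then 1.06, 1.08, and Cyba at 2.27, 2.21, 2.37 and then -7.72, -7.89, in log2 units relative to the array's 75th percentile. Slc16a3 stood at -4.20, -4.24, -4.09 and then 0.85, 0.99. These examples were chosen after their values were seen. The melanocyte channel gene Trpm1 was low in the first 3 (-3.37, -3.09, -3.31) and higher in the others (1.09, 1.04). Lgals3 went the other way (1.75, 1.77, 1.67 against -2.72, -2.58). No 4-fold gap was seen for Tnfaip3 (-6.03, -5.65, -5.86, -5.71, -5.34) or Ccl5 (3.35, 3.27, 3.15, 2.81, 3.02).

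**Figure D3:**
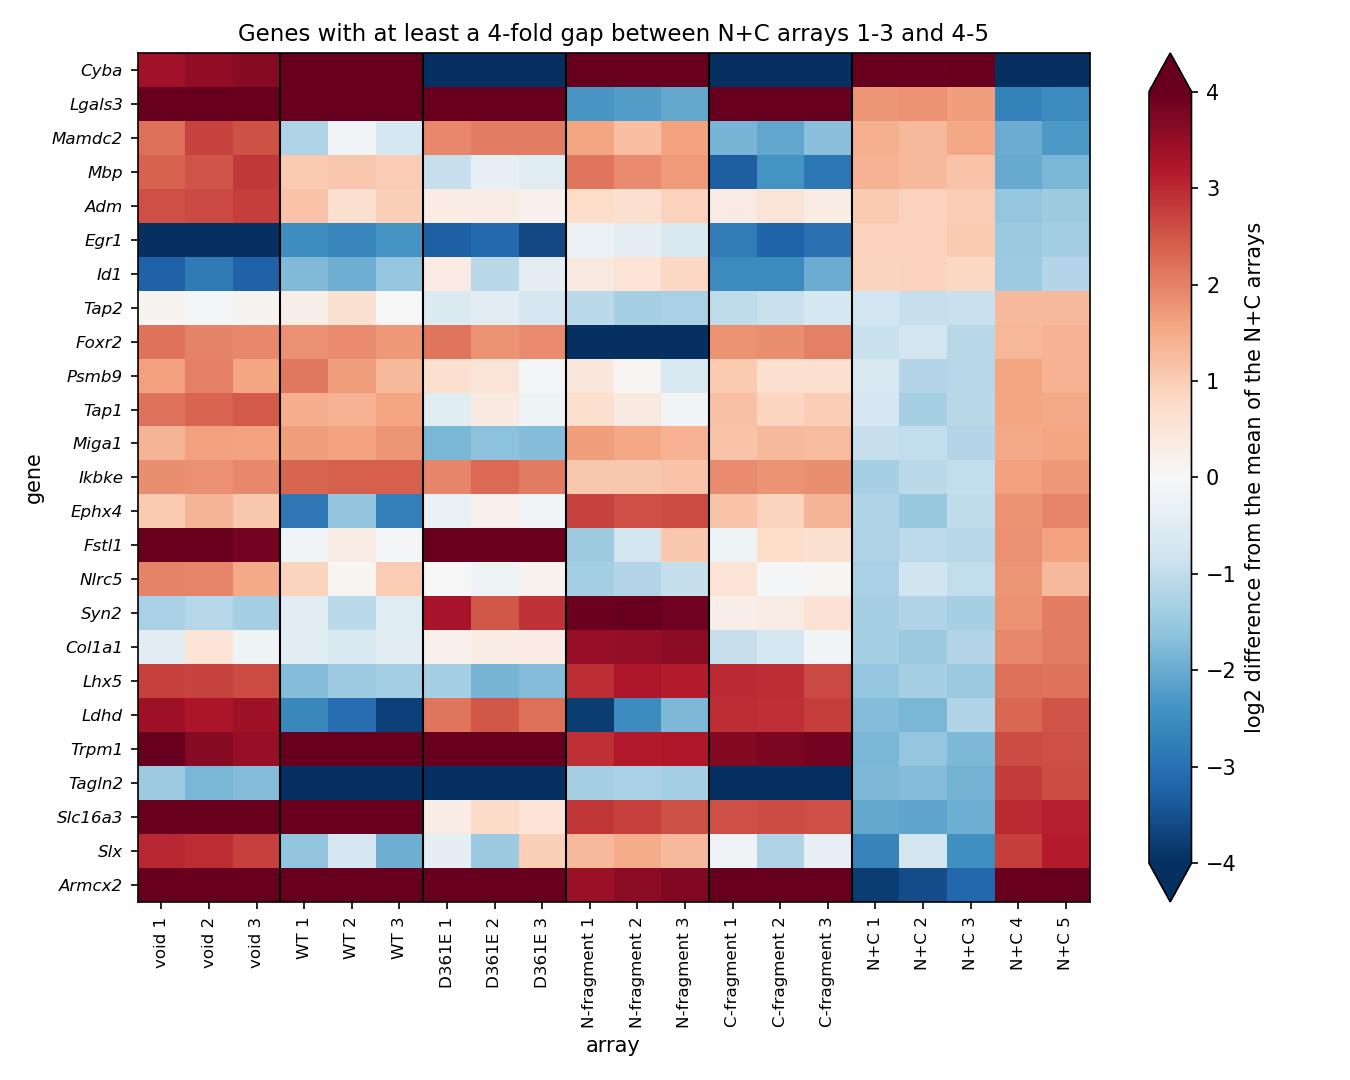
Some of the named genes with a gap of at least 4-fold between N+C arrays 1 to 3 and N+C arrays 4 and 5, shown as log2 difference from the N+C mean, with the colour saturating at 4 log2 units.

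In the cell cycle list 16 of 29 measured members rose, 0 fell and 13 were not called (adjusted p = 1.16e-09, adjusted p = 0.0283 with an estimated correlation). E2f1 (log2 0.82 ± 0.10) and the cyclin Ccnd1 (log2 0.78 ± 0.08) were among those up. For p53 targets 0 of 19 measured members rose, 15 fell and 4 were not called (adjusted p = 1.59e-11, adjusted p = 0.00272 with an estimated correlation). Trp53inp1 (log2 -2.92 ± 0.07) and Perp (log2 -2.48 ± 0.31, above background on 3 of 5 N+C arrays) fell. Among NRF2 targets 9 of 17 measured members rose, 0 fell and 8 were not called (adjusted p = 5.6e-06, adjusted p = 0.0304 with an estimated correlation). The mesenchymal genes rose as a list, where 8 of 14 measured members rose, 0 fell and 6 were not called (adjusted p = 9.68e-05, adjusted p = 0.0304 with an estimated correlation). The matricellular Ccn1 rose (log2 2.43 ± 0.10). The preset correlation alone called the glycolysis and hypoxia genes (0 of 18 higher, 9 lower, adjusted p = 4.18e-05, adjusted p = 0.318 with an estimated correlation). Cholesterol synthesis genes had that call too (0 of 21 higher, 9 lower, adjusted p = 0.00176, adjusted p = 0.707 with an estimated correlation). Immediate early genes were called likewise (6 of 16 higher, 2 lower, adjusted p = 0.0147, adjusted p = 0.391 with an estimated correlation). Without arrays 1 to 3 the cholesterol list pointed up (adjusted p = 0.606) and the immediate early list was not called (adjusted p = 0.395). NF-kB family genes were called lower by fry (adjusted p = 0.0029) but not by camera (1 of 19 higher, 7 lower, adjusted p = 0.109), and the 1 that rose was the ubiquitin ligase gene Birc2 (log2 0.44 ± 0.10). Members of the called lists higher and lower when adjusted over the list alone numbered, in the same order, 18 and 0, 0 and 15, 9 and 1, 8 and 1, 1 and 10, 0 and 9, 8 and 2. None of the 14 remaining lists was called by camera (adjusted p from 0.0988 to 0.896). Median, mean and test differed in sign for NF-kB inflammatory targets (median -0.07, mean -0.04, test up) and haematopoietic and B-lymphoid markers (median -0.19, mean -0.04, test up). In a fit with slide as a block 6266 genes were called, among them 4461 of the 4601 in the same direction. On unscaled values the division was 4675 higher and 890 lower, with the median of all genes at log2 0.19. With arrays left out because of their measured values, the count was 6316 without arrays 4 and 5 and 5297 without arrays 1 to 3, with 12 and 5 lists called.

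Compared with WT, NRF2 targets and mesenchymal genes were higher with D361E, and p53 targets were lower. Nqo1 rose further (2.84-fold, log2 1.51 ± 0.26, adjusted p = 0.00227), as did Srxn1 (log2 0.98 ± 0.10), and the matrix protein gene Tgfbi was at least 3.62-fold higher (adjusted p = 0.00042). Tnfaip3 (log2 0.79 ± 0.15) and Nfkbia (log2 0.74 ± 0.11) were higher than with WT, whereas Bcl3 was lower (log2 -1.0 ± 0.16). Ldhd was at least 16.6-fold higher (adjusted p = 0.0036) and Fstl1, a follistatin-like secreted factor, was at least 14.3-fold higher (adjusted p = 0.00227). Cyba was at least 386-fold lower (adjusted p = 0.0171), Col4a1 was at least 7.34-fold lower (adjusted p = 1.12e-12), and Kbtbd11, a BTB-kelch gene, fell (log2 -4.26 ± 0.32, above background on 1 of 3 D361E arrays). Altogether 788 of 18738 genes changed (n = 3 and 3), 453 upward and 335 downward, with 185 changed at least 2-fold.

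For NRF2 targets 7 of 17 measured members rose, 0 fell and 10 were not called (adjusted p = 6.27e-09, adjusted p = 0.016 with an estimated correlation). In the mesenchymal list 4 of 14 measured members rose, 0 fell and 10 were not called (adjusted p = 1.67e-06, adjusted p = 0.016 with an estimated correlation). Ccn2 (log2 1.5 ± 0.18) came after Tgfbi. Among p53 targets 0 of 19 measured members rose, 4 fell and 15 were not called (adjusted p = 1.39e-05, adjusted p = 0.0311 with an estimated correlation). Plk2 was at least 1.73-fold lower (adjusted p = 0.00039), and Btg2 fell (log2 -0.99 ± 0.14). Called only with the preset correlation were the interferon-stimulated genes (0 of 27 higher, 5 lower, adjusted p = 1.69e-05, adjusted p = 0.314 with an estimated correlation). Genes of the unfolded protein and integrated stress response had that call too (0 of 24 higher, 8 lower, adjusted p = 2.78e-07, adjusted p = 0.127 with an estimated correlation). Glycolysis and hypoxia genes were called likewise (0 of 18 higher, 7 lower, adjusted p = 3.51e-10, adjusted p = 0.062 with an estimated correlation). The interferon regulator Irf7 was at least 2.11-fold lower (adjusted p = 0.0262) and Rtp4 fell (log2 -1.74 ± 0.32). In the stress list Atf3, an ATF/CREB factor, fell (log2 -1.06 ± 0.13) with Trib3 (log2 -0.98 ± 0.18). The hypoxia-induced Bnip3 (log2 -1.99 ± 0.14) and the angiogenic factor Vegfa (log2 -1.80 ± 0.15) were lower. Adjusted over the list alone, the called lists had, in the order given, 10 and 0, 8 and 0, 0 and 4, 2 and 10, 0 and 11, 1 and 8 members higher and lower. Not called by camera were the 15 other lists (adjusted p from 0.0607 to 0.998). The sign differed between median, mean and test for NF-kB inflammatory targets (median -0.05, mean -0.10, test up), fibroblast markers (median 0.10, mean 0.09, test down), cell cycle genes (median 0.09, mean -0.02, test up) and cholesterol synthesis genes (median -0.12, mean 0.08, test down). Blocking on slide, 871 genes were called, among them 587 of the 788 in the same direction. The count was 486 without WT 1, 469 without WT 2, 476 without D361E 3. Left unscaled, the arrays gave 130 higher and 1274 lower genes, with the median of all genes at log2 -0.24.

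Mesenchymal genes were higher with the N-fragment than with WT, and Dkk3 and galectin-3 were lower. The neurotrophin receptor gene Ngfr was at least 32.4-fold higher (adjusted p = 3.74e-11), Olfr875 was at least 16.9-fold higher (adjusted p = 3.24e-14), and the collagen chaperone gene Fkbp10 was at least 35.3-fold higher (adjusted p = 2.31e-09). Megf10 rose (log2 6.45 ± 0.48, above background on 2 of 3 WT arrays). Ccl5 rose (12.8-fold, log2 3.68 ± 0.17, adjusted p = 2.31e-10), Birc3 was at least 3.16-fold higher (adjusted p = 0.000105) and its relative Birc2 rose (log2 1.54 ± 0.12). Cxcl1 was at least 5.28-fold lower (adjusted p = 4.24e-05), and Bcl3 (log2 -1.47 ± 0.16) and the NF-kB subunit gene Relb (log2 -0.75 ± 0.11) fell. Dkk3 was at least 176-fold lower (adjusted p = 9.16e-11), the torsin-family gene Tor4a was at least 49.1-fold lower (adjusted p = 4.71e-12) and Capn6 was at least 20.5-fold lower (adjusted p = 4.18e-13), and Lgals3 fell (log2 -6.76 ± 1.00). Rela was higher (log2 0.28 ± 0.07, adjusted p = 0.00566). Changed genes numbered 5121 of 18738, 2584 higher and 2537 lower, 1092 of them at least 2-fold (n = 3 and 3).

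The mesenchymal list was the 1 called under both correlations, since 11 of 14 measured members rose, 1 fell and 2 were not called (adjusted p = 1.94e-06, adjusted p = 0.025 with an estimated correlation). Fn1 was high (log2 3.28 ± 0.43) and Tgfb1 low (log2 -1.47 ± 0.50). The preset correlation alone called the fibroblast markers (4 of 6 higher, 1 lower, adjusted p = 0.00508, adjusted p = 0.171 with an estimated correlation). Cell cycle genes had that call too (14 of 29 higher, 1 lower, adjusted p = 0.000552, adjusted p = 0.171 with an estimated correlation). Genes of the unfolded protein and integrated stress response were called likewise (1 of 24 higher, 15 lower, adjusted p = 1.94e-06, adjusted p = 0.171 with an estimated correlation). NRF2 targets joined them (7 of 17 higher, 1 lower, adjusted p = 0.00599, adjusted p = 0.171 with an estimated correlation). Cholesterol synthesis genes were a further case (1 of 21 higher, 15 lower, adjusted p = 4.7e-06, adjusted p = 0.413 with an estimated correlation). Immediate early genes had that call too (9 of 16 higher, 1 lower, adjusted p = 0.000163, adjusted p = 0.171 with an estimated correlation). Ribosomal protein genes were called likewise (2 of 22 higher, 0 lower, adjusted p = 0.025, adjusted p = 0.602 with an estimated correlation). The fibroblast list again pointed down with probes above background on all arrays (adjusted p = 0.433). Among the stress genes Chac1 (log2 -2.46 ± 0.21) and Trib3 (log2 -2.34 ± 0.18) fell and Ppp1r15a, a phosphatase subunit, rose (log2 0.35 ± 0.11). Cholesterol genes such as Fdps (log2 -1.03 ± 0.12) and Dhcr7 (log2 -1.0 ± 0.20) fell. Myc rose (log2 1.30 ± 0.21) with Egr1 (log2 2.10 ± 0.56). NF-kB family genes moved both ways (4 of 19 higher, 5 lower, adjusted p = 0.92). In the anti-apoptotic list 4 of 10 rose and 0 fell (adjusted p = 0.067), among them Gadd45b (log2 1.90 ± 0.11). In the order given, 11 and 1, 4 and 1, 14 and 1, 1 and 17, 7 and 1, 1 and 16, 10 and 1, 0 and 0 members of the called lists were higher and lower when adjusted over the list alone. The 13 other lists were not called by camera (adjusted p from 0.0527 to 0.995). Signs differed between median, mean and test for melanocyte markers (median 0.02, mean -0.11, test down), p53 targets (median -0.12, mean -0.16, test up) and STAT5 targets (median -0.11, mean 0.20, test down). With slide as a block 6297 genes were called, among them 4790 of the 5121 in the same direction. Without scaling between arrays 1556 genes were higher and 2422 lower.

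The C-fragment stood below WT in NF-kB feedback and stress-response genes. Tnfaip3 was at least 13.6-fold lower (adjusted p = 5.05e-11), Cxcl1 was at least 5.4-fold lower (adjusted p = 4.86e-05), and Bcl3 (6.86-fold, log2 -2.78 ± 0.16, adjusted p = 2.48e-08) and Cxcl10 (log2 -2.92 ± 0.08, adjusted p = 1.2e-12) fell. Casp4, an inflammatory caspase, fell (log2 -5.13 ± 0.97, above background on 1 of 3 C-fragment arrays). Ldhd was at least 25.3-fold higher (adjusted p = 0.00214), the homeobox gene Lhx5 was at least 5.58-fold higher (adjusted p = 0.00653), and Gas6, a ligand of TAM receptors, was at least 4.94-fold higher (adjusted p = 0.0028). Cyba was at least 302-fold lower (adjusted p = 0.0177) and Capn6 was at least 21-fold lower (adjusted p = 1.2e-12). Altogether 832 of 18738 genes changed (n = 3 and 3), 391 upward and 441 downward, with 147 changed at least 2-fold.

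Of the NF-kB family and feedback genes 0 of 19 measured members rose, 8 fell and 11 were not called (adjusted p = 4.42e-14, adjusted p = 0.00459 with an estimated correlation). Within the unfolded protein and integrated stress response 0 of 24 measured members rose, 15 fell and 9 were not called (adjusted p = 5.76e-24, adjusted p = 0.00459 with an estimated correlation). Atf3 (log2 -1.39 ± 0.13) and Chac1 (log2 -1.11 ± 0.21) were lowest. Called only with the preset correlation were the NF-kB inflammatory targets (0 of 16 higher, 4 lower, adjusted p = 0.014, adjusted p = 0.0743 with an estimated correlation). MHC class I genes had that call too (0 of 14 higher, 2 lower, adjusted p = 0.00214, adjusted p = 0.233 with an estimated correlation). Interferon-stimulated genes were called likewise (0 of 27 higher, 0 lower, test down, adjusted p = 0.00939, adjusted p = 0.469 with an estimated correlation). Melanocyte markers joined them (1 of 16 higher, 0 lower, adjusted p = 0.0193, adjusted p = 0.152 with an estimated correlation). Cell cycle genes were a further case (1 of 29 higher, 0 lower, adjusted p = 0.00939, adjusted p = 0.233 with an estimated correlation). Targets of p53 had that call too (1 of 19 higher, 0 lower, adjusted p = 0.0305, adjusted p = 0.233 with an estimated correlation). NRF2 targets were called likewise (2 of 17 higher, 0 lower, adjusted p = 0.000382, adjusted p = 0.104 with an estimated correlation). Glycolysis and hypoxia genes joined them (1 of 18 higher, 6 lower, adjusted p = 0.000245, adjusted p = 0.233 with an estimated correlation). Cholesterol synthesis genes were a further case (1 of 21 higher, 0 lower, test down, adjusted p = 0.0147, adjusted p = 0.595 with an estimated correlation). Ribosomal protein genes had that call too (0 of 22 higher, 0 lower, test up, adjusted p = 4.16e-06, adjusted p = 0.233 with an estimated correlation). In the MHC list Tapbp, which loads peptide onto class I molecules (log2 -1.30 ± 0.10), and the light chain gene B2m (log2 -0.58 ± 0.13) fell. Bnip3 (log2 -1.82 ± 0.14) and the kinase gene Pdk1 (log2 -0.90 ± 0.10) fell in the glycolysis list and Car9 rose (log2 0.56 ± 0.07). Members of the called lists higher and lower when adjusted over the list alone numbered, in the same order, 0 and 10, 0 and 19, 1 and 4, 0 and 2, 0 and 0, 2 and 0, 1 and 0, 2 and 1, 2 and 0, 1 and 8, 1 and 1, 0 and 0. None of the 9 remaining lists was called by camera (adjusted p from 0.0744 to 0.911). Median, mean and test differed in sign for anti-apoptotic genes (median 0.04, mean 0.01, test down) and macrophage markers (median -0.001, mean 0.14, test up). In a fit with slide as a block 1699 genes were called, among them 819 of the 832 in the same direction. A fit with only these 6 arrays called 2299 genes. The count was 395 without WT 1, 444 without WT 2, 410 without C-fragment 1, 442 without C-fragment 2, 436 without C-fragment 3. On unscaled values the division was 74 higher and 866 lower, with the median of all genes at log2 -0.15.

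With N+C Tnfaip3 and Cxcl1 were again lower than with WT and Ccl5 was higher, but every list call was lost with an estimated correlation. Tnfaip3 fell (14.9-fold, log2 -3.90 ± 0.13, adjusted p = 2.14e-11, above background on 1 of 5 N+C arrays), and Cxcl1 was at least 6.62-fold lower (adjusted p = 7.28e-07) while Ccl5 rose (log2 3.12 ± 0.15, adjusted p = 9.97e-10). Zfp521 (log2 5.73 ± 0.40, above background on 1 of 3 WT arrays), Lims2 (log2 4.64 ± 0.22) and Megf10 (log2 4.49 ± 0.43, above background on 2 of 3 WT arrays) rose. Capn6 was at least 25.7-fold lower (adjusted p = 9.03e-14), Krba1 was at least 18.7-fold lower (adjusted p = 3.07e-16), and Armcx2 (log2 -6.01 ± 1.78, above background on 2 of 5 N+C arrays) fell. Changed genes numbered 4360 of 18738, 2548 higher and 1812 lower, 686 of them at least 2-fold (n = 5 and 3).

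The list calls that follow rest on the preset correlation. For the NF-kB family and feedback genes 0 of 19 measured members rose, 9 fell and 10 were not called (adjusted p = 4.7e-06, adjusted p = 0.0753 with an estimated correlation). It was also called without arrays 4 and 5 (adjusted p = 6.89e-06) and without arrays 1 to 3 (adjusted p = 0.000338). Of the MHC class I genes 0 of 14 measured members rose, 5 fell and 9 were not called (adjusted p = 0.00281, adjusted p = 0.347 with an estimated correlation). H2-K1, a class I heavy chain gene (log2 -1.87 ± 0.45), differed between the N+C sets, at -3.12, -2.88, -2.92 in arrays 1 to 3 and -0.67, -0.97 in arrays 4 and 5, beside -0.16, -0.19, -0.38 with WT. Without arrays 1 to 3 the list was not called (adjusted p = 0.551). Lower as well was the unfolded protein and integrated stress response (0 of 24 higher, 15 lower, adjusted p = 1.37e-08, adjusted p = 0.0935 with an estimated correlation). Glycolysis and hypoxia genes (2 of 18 higher, 7 lower, adjusted p = 0.00249, adjusted p = 0.406 with an estimated correlation) and cholesterol synthesis genes followed (1 of 21 higher, 11 lower, adjusted p = 1.23e-05, adjusted p = 0.406 with an estimated correlation). Cell cycle genes pointed up (14 of 29 higher, 1 lower, adjusted p = 5.82e-05, adjusted p = 0.121 with an estimated correlation). So did NRF2 targets (9 of 17 higher, 0 lower, adjusted p = 0.00205, adjusted p = 0.121 with an estimated correlation) and immediate early genes (9 of 16 higher, 0 lower, adjusted p = 4.61e-05, adjusted p = 0.0935 with an estimated correlation). Mesenchymal genes (9 of 14 higher, 1 lower, adjusted p = 5.72e-05, adjusted p = 0.0753 with an estimated correlation) and ribosomal genes (3 of 22 higher, 0 lower, adjusted p = 0.0111, adjusted p = 0.524 with an estimated correlation) did as well. Without arrays 1 to 3 the calls of cholesterol (adjusted p = 0.332), glycolysis (adjusted p = 0.107) and ribosomal genes (adjusted p = 0.122) were lost too, and without arrays 4 and 5 those of NRF2 targets (adjusted p = 0.118) and ribosomal genes (adjusted p = 0.0531). The ribosomal list pointed down with quantile normalization (adjusted p = 0.52), also after background correction (adjusted p = 0.717). Egr1 (log2 2.50 ± 0.50) and the AP-1 gene Fos (log2 1.82 ± 0.23) rose, and Ccnd1 rose (log2 1.07 ± 0.08). The stress genes Chac1 (log2 -1.86 ± 0.19) and Trib3 (log2 -1.48 ± 0.16) fell. Cd68, a macrophage lysosomal marker, rose (log2 1.75 ± 0.14), and Trpm1 fell (log2 -4.28 ± 0.89). Adjusted over the list alone, the called lists had, in the order given, 0 and 9, 0 and 7, 0 and 15, 3 and 8, 1 and 13, 16 and 1, 9 and 1, 9 and 0, 11 and 2, 3 and 0 members higher and lower. Not called by camera were the 11 other lists (adjusted p from 0.0671 to 0.974). The sign differed between median, mean and test for melanocyte markers (median 0.04, mean -0.29, test down), fibroblast markers (median -0.03, mean -0.15, test up) and STAT5 targets (median -0.05, mean 0.15, test down). Blocking on slide, 5047 genes were called, among them 3714 of the 4360 in the same direction. Without arrays 4 and 5 the count was 6027 and without arrays 1 to 3 it was 5168, with 9 and 6 lists called. Left unscaled, the arrays gave 858 higher and 3150 lower genes, with the median of all genes at log2 -0.19.

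With both fragments 4327 of 18738 genes departed from the sum of both fragment effects on the log2 scale, 2687 above and 1640 below. A void or other cell population that differs could give this too. N+C had 5 arrays and N-fragment, C-fragment and void 3 each. Birc3, above background on the 3 N-fragment arrays and no other of these 14, lay below the sum (adjusted p = 0.00377). So did Tnfaip3 (adjusted p = 1.13e-05), with group means for N+C, N-fragment, C-fragment and void of -5.72, -2.36, -6.0 and -4.42 in log2 units and 1, 3, 0, 3 arrays above background. Dkk3 lay above it (adjusted p = 1.87e-08), with means of 1.08, -6.74, 1.5 and 1.83 in the same order and no N-fragment array above background. The ankyrin repeat gene Asb2 lay above it as well (adjusted p = 4.46e-10, means -2.19, -7.48, -5.25 and -2.30, arrays above background 5, 0, 2, 3).

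Of the p53 targets 11 of 19 measured members lay above the sum, 1 below it and 7 were not called (adjusted p = 0.00909, adjusted p = 0.363 with an estimated correlation). Btg2 (log2 2.10 ± 0.19) was above and Ei24 (log2 -1.0 ± 0.14) below. Most of these genes fell with either fragment and with N+C, and a change of the same size in all 3 groups enters this comparison with its sign turned. Of the 253 genes lower with all 5 constructs 221 lay above the sum, and of the 152 higher with all 5, 134 lay below it. Of the NRF2 targets 0 of 17 measured members lay above the sum, 7 below it and 10 were not called (adjusted p = 0.00318, adjusted p = 0.363 with an estimated correlation). For NF-kB family and feedback genes 1 of 19 measured members lay above it, 6 below it and 12 were not called (adjusted p = 0.00909, adjusted p = 0.421 with an estimated correlation). Bcl3 was the 1 above the sum (log2 0.82 ± 0.21). Cell cycle genes had 3 members above and 5 below the sum among 29 (adjusted p = 0.00909, adjusted p = 0.421 with an estimated correlation). Top2a, the topoisomerase of dividing cells (log2 -0.81 ± 0.16), and the cyclin Ccnb1 (log2 -0.82 ± 0.07) were below. In the glycolysis and hypoxia list 7 of 18 measured members lay above it, 1 below it and 10 were not called (adjusted p = 0.00909, adjusted p = 0.488 with an estimated correlation). Bnip3 (log2 1.68 ± 0.19) was above and Car9 (log2 -0.87 ± 0.10) below. In the pro-apoptotic list Bbc3 lay above it (log2 1.16 ± 0.17). In the order given, 11 and 3, 0 and 7, 1 and 6, 3 and 6, 7 and 1 members of the called lists were higher and lower when adjusted over the list alone. The 16 other lists were not called by camera (adjusted p from 0.171 to 0.93). Signs differed between median, mean and test for immediate early genes (median -0.03, mean 0.15, test down) and STAT5 targets (median 0.28, mean -0.14, test up). In a fit with slide as a block 4531 genes were called, among them 3428 of the 4327 in the same direction. Without arrays 4 and 5 there were 6348 genes and 8 lists, and without arrays 1 to 3 5303 and 6, the NF-kB family (adjusted p = 0.135) and cell cycle lists (adjusted p = 0.106) no longer among them. Without scaling between arrays 912 genes were higher and 4391 lower, with the median of all genes at log2 -0.32.

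No 2 profiles against void passed their highest simulated correlation. This cannot show a lack of likeness, as construct-specific changes, not simulated, can lower r. N+C residuals, whose 2 sets differ, may raise simulated r. WT and the C-fragment had the highest correlation (r = 0.70, simulated 0.48, covariance 0.187 against 0.064, highest simulated 0.84 and 0.219). Both raised 321 genes (expected 29.5) and both lowered 609 (expected 95.2), Nqo1 and Tubb2b up and Aspg and Tagln2 down among them. The N-fragment and N+C followed (r = 0.65, simulated 0.53, covariance 0.246 against 0.064, highest simulated 0.86 and 0.233), with 1316 genes higher in both (expected 291) and 1575 lower in both (expected 429), such as Ccl5 and Id1 up and Lgals3 and Trp53inp1 down. WT and D361E came next (r = 0.58, simulated 0.47, covariance 0.152 against 0.063), then C-fragment and D361E (r = 0.55, simulated 0.50, covariance 0.152 against 0.067), C-fragment and N+C (r = 0.53, simulated 0.54, covariance 0.155 against 0.065) and D361E and N+C (r = 0.51, simulated 0.56, covariance 0.144 against 0.066). The lower values were those of the N-fragment with the C-fragment (r = 0.49, simulated 0.47, covariance 0.182 against 0.065) and with D361E (r = 0.47, simulated 0.48, covariance 0.167 against 0.065), and of WT with N+C (r = 0.43, simulated 0.55, covariance 0.119 against 0.065) and with the N-fragment (r = 0.40, simulated 0.46, covariance 0.141 against 0.06). Covariance passed its highest simulated value for the N-fragment and N+C alone, and the expected overlaps do not allow for the shared void arrays.

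Of the 8488 genes changed against void with at least 1 construct, 405 changed alike with all 5, 152 higher and 253 lower, and 10 of the 19 measured p53 targets were among the lower ones. Bbc3 fell with each of them, from -0.69 ± 0.13 with WT to -1.20 ± 0.13 with the N-fragment on the log2 scale. Nqo1, among the higher ones, was above background on all arrays of every construct and on no void array. Without void array 1, 2 or 3 the number was 371, 233 or 232.

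**Figure D4:**
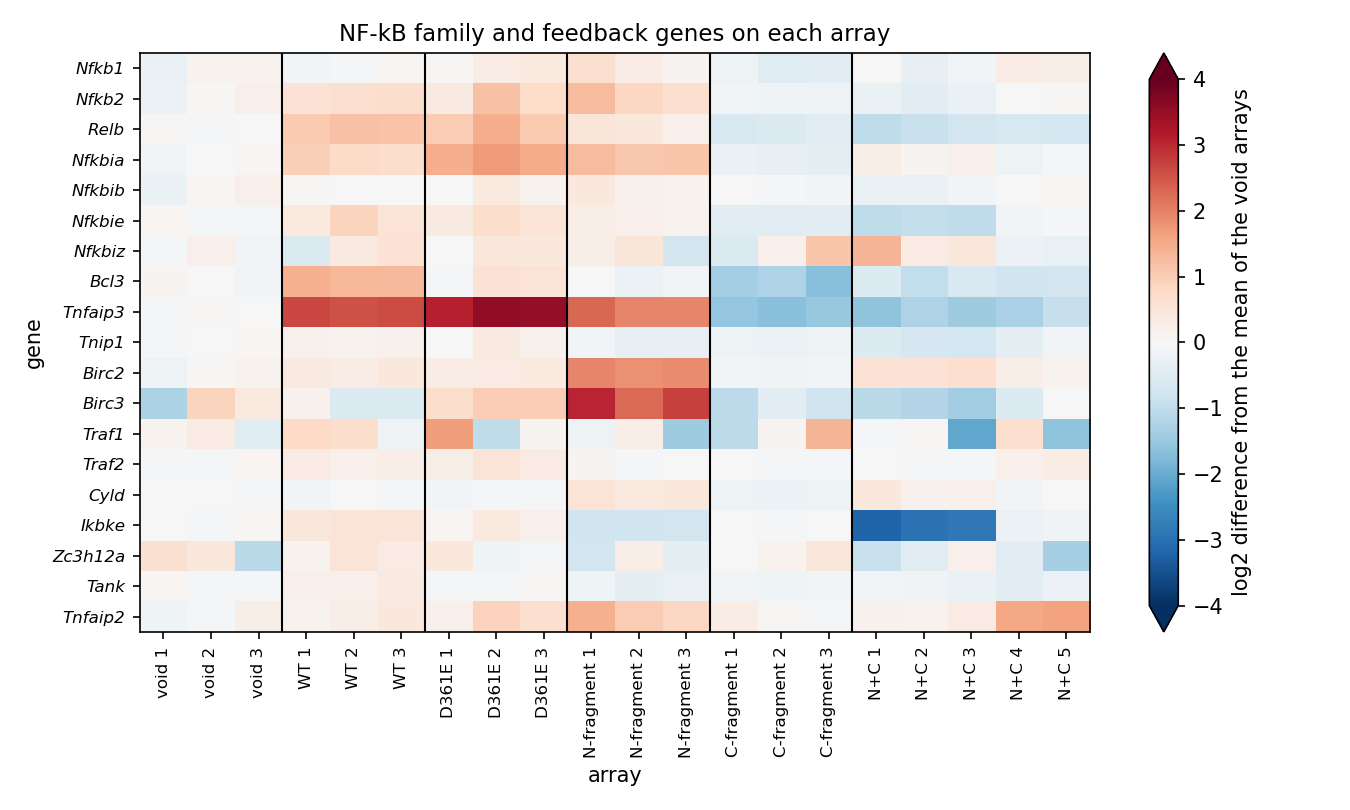
NF-kB family and feedback genes on each array as log2 difference from the void mean, with the colour saturating at 4 log2 units.

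The 6 lists that follow were called by camera in no comparison, though fry called some of them. By camera adjusted p ranged from 0.0595 to 0.991 for anti-apoptotic genes, 0.211 to 0.995 for pro-apoptotic genes, 0.0744 to 0.896 for haematopoietic and B-lymphoid markers, 0.078 to 0.984 for macrophage markers, 0.225 to 0.922 for epithelial markers and 0.078 to 0.984 for STAT5 targets. Single members still moved: the leukocyte actin-bundling gene Lcp1 rose with N+C (log2 1.28 ± 0.11) and fell with the N-fragment (log2 -1.92 ± 0.12) against void. Coro1a rose with D361E (log2 1.12 ± 0.27). Of the STAT5 targets Id1 rose with D361E (log2 2.71 ± 0.57), the N-fragment (log2 3.68 ± 0.57) and N+C (log2 3.1 ± 0.51), and Ccnd2, a D-type cyclin, fell with WT (log2 -0.44 ± 0.11) and D361E (log2 -0.63 ± 0.11).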

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

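The tests of the 3 patterns below and the other divisions of the arrays were chosen only after the results were seen, while the critical value for a far array and the beyond-the-sum comparison were set before. Of 87 measures tested for a far array 2 passed, with 4.35 expected by chance. The mean score of the anti-apoptotic genes placed N+C array 4 far from the other N+C arrays (ratio of gap to range 0.73). The level of Gadd45b placed N+C array 5 far from the others (0.732). N+C differed from the sum of both fragments in 4327 genes and 5 lists (0 lists with an estimated correlation).

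N+C arrays 1 to 3 and arrays 4 and 5 formed 2 sets, with 224 genes at least 4-fold apart. A slide effect was excluded, since N+C 1 and N+C 4, which shared a slide, set against the others gave 4 such genes. Arrays of another group of this series under the N+C label were also excluded, as each set was at least 111 genes away from every other group. The 224 genes exceeded the 34 to 88 among void, WT, D361E and C-fragment, and N-fragment with these gave 179 to 231. Separate cell populations with the same constructs fit, but the labels name no clones or pools and the test cannot tell.

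NF-kB family and feedback genes were lower with the C-fragment and with N+C than with WT, though the list call for N+C was lost with an estimated correlation (adjusted p = 0.0753). For the C-fragment slide was excluded (adjusted p = 2e-12 with slide as a block). Other scalings gave at most 2.56e-13, but a shift of all genes largely cancels in camera. Mean list scores were -1.42 (void), -0.92 (WT), -0.82 (D361E), -0.93 (N-fragment), -1.72 (C-fragment) and -1.76 (N+C). On slides 3 and 4 WT arrays scored -0.898 and -0.924 and N+C arrays -1.896 and -1.92, which argues against slide for N+C. Unscaled, all genes had medians of -0.148 (C-fragment) and -0.188 (N+C) against WT, beside scaled list means of -0.796 and -0.841. This argues against scaling. Cell population differences unrelated to the construct remain possible. The N+C sets differed by 0.301, and the test cannot tell this from an effect of the C-fragment.

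The 405 genes changed alike against void with all 5 constructs, among them 10 p53 targets, were set beside simulations with no effect. Those gave at most 0 such genes, as calls in all 5 comparisons are then hardly possible, so they cannot tell how much chance spread of the shared void arrays adds. Slide did not explain the 405, with 531 such genes when slide was a block. A void population that differs from the others fits: setting each other group against all remaining groups gave 57 genes for WT, 165 for D361E, 50 for the C-fragment, 456 for N+C and 1464 for the N-fragment. A general response to expressing any p65 construct would give the same pattern, and the data do not separate these explanations.

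Divisions of 6 arrays into groups of 3 number only 10, so no share under 0.05 was possible there. Counting the real division itself, those that changed as many genes were 1 of 10 for WT vs void (real 1759, highest other 0), 1 of 10 for D361E vs void (real 2527, highest other 4), 1 of 10 for N-fragment vs void (real 5829, highest other 0), 1 of 10 for C-fragment vs void (real 2460, highest other 0), 1 of 10 for D361E vs WT (real 788, highest other 2), 1 of 10 for N-fragment vs WT (real 5121, highest other 2), 1 of 10 for C-fragment vs WT (real 832, highest other 1). Divisions with as many lists called were 2 of 10 for WT vs void (real 7, highest other 7), 1 of 10 for D361E vs void (real 11, highest other 8), 1 of 10 for N-fragment vs void (real 9, highest other 8), 1 of 10 for C-fragment vs void (real 6, highest other 5), 3 of 10 for D361E vs WT (real 6, highest other 8), 1 of 10 for N-fragment vs WT (real 8, highest other 7), 1 of 10 for C-fragment vs WT (real 12, highest other 9). For N+C against void 2 of 56 divisions changed as many genes, the real one included (real 4601, highest other 4713), and against WT 2 of 56 (real 4360, highest other 4402); both of the higher ones put N+C 1 to 3 on one side and N+C 4 and 5 with the 3 arrays of the other group, and so followed the N+C sets. As many lists as the real 7 and 10 were called in 18 and 5 of 56 (highest other 10 and 11), so a chance origin of those list counts was not excluded. For the beyond-the-sum comparison 1 of 100, the real labels themselves, reached the real 4327 genes (highest other 1738) and 46 of 100 the real 5 lists (highest other 9), so its number of lists is no more than label draws give.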

How the results depend on the processing

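All alternatives were set beforehand, except the 2 fits leaving out N+C arrays by their measured values, chosen after seeing the data. No count of genes or lists stayed within 1.5 times its value under every alternative; 24 of 81 list calls, 330 of 533 named genes and 4 of 10 correlations kept direction and side of the threshold (correlations their value) under every alternative run for them, which for correlations were 2. Quantile normalization, the filter on all arrays, the mean of probes and trend with robust moderation moved no count over 1.5 times. The 4 correlations that kept their value did so with no filter, under which the other 6 moved. Signal over background limits the folds: 51.1 to 57.9% of spots were well above it, and genes absent in a group have only a lower bound. Scan date as a block was not run, since scan time and slide coincide. Same direction but no longer called were 13 of 81 list calls and 74 of 533 named genes on unscaled values, 7 of 81 list calls and 37 of 533 named genes with quantile normalization, 4 of 81 list calls and 101 of 533 named genes with only the groups compared and 5 of 81 list calls and 53 of 533 named genes with slide as a block. Leaving out 1 array did this in 18 of 560 list calls and 481 of 3932 named genes, and an estimated correlation in 55 of 81 list calls.

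Changed genes numbered 1759 for WT vs void, 2527 for D361E vs void, 5829 for N-fragment vs void, 2460 for C-fragment vs void, 4601 for N+C vs void, 788 for D361E vs WT, 5121 for N-fragment vs WT, 832 for C-fragment vs WT, 4360 for N+C vs WT, 4327 for beyond the sum. Numbers that moved over 1.5 times follow by alternative. With unscaled values 7678 for WT vs void, 1404 for D361E vs WT. With no filter 1116 for WT vs void, 522 for D361E vs WT, 469 for C-fragment vs WT. With array weights 6724 for WT vs void, 7190 for D361E vs void, 9421 for N-fragment vs void, 7738 for C-fragment vs void, 8191 for N+C vs void, 6641 for D361E vs WT, 8700 for N-fragment vs WT, 4738 for C-fragment vs WT, 8081 for N+C vs WT, 8915 for beyond the sum. With a 2-fold minimum 285 for WT vs void, 453 for D361E vs void, 1316 for N-fragment vs void, 431 for C-fragment vs void, 706 for N+C vs void, 185 for D361E vs WT, 1092 for N-fragment vs WT, 147 for C-fragment vs WT, 686 for N+C vs WT, 1224 for beyond the sum. With only the groups compared 1451 for D361E vs void, 2023 for N+C vs void, 2299 for C-fragment vs WT, 2645 for N+C vs WT. With normexp with quantile normalization 541 for C-fragment vs WT. With slide as a block 1699 for C-fragment vs WT. A 2-fold minimum calls fewer genes by construction; for the other shifts the cause was not tested.

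Lists called numbered 7 for WT vs void, 11 for D361E vs void, 9 for N-fragment vs void, 6 for C-fragment vs void, 7 for N+C vs void, 6 for D361E vs WT, 8 for N-fragment vs WT, 12 for C-fragment vs WT, 10 for N+C vs WT, 5 for beyond the sum. Those that moved were 6 for C-fragment vs WT with unscaled values; 8 for beyond the sum with no filter; 11 for N+C vs void with array weights; 4 for WT vs void, 6 for D361E vs void, 4 for N-fragment vs void, 2 for C-fragment vs void, 4 for N+C vs void, 3 for D361E vs WT, 1 for N-fragment vs WT, 2 for C-fragment vs WT, 0 for N+C vs WT, 0 for beyond the sum with an estimated correlation; 14 for N-fragment vs void, 12 for N+C vs void, 14 for N-fragment vs WT, 12 for beyond the sum with fry; 12 for N+C vs void, 8 for beyond the sum with N+C without arrays 4 and 5; 8 for beyond the sum with normexp with quantile normalization; 6 for N+C vs WT with N+C without arrays 1 to 3. The cause was not tested.

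Leaving out 1 array gave gene counts of 941 to 1722 for WT vs void, 1720 to 2240 for D361E vs void, 4767 to 5531 for N-fragment vs void, 1434 to 2501 for C-fragment vs void, 3466 to 5055 for N+C vs void, 469 to 635 for D361E vs WT, 4057 to 4536 for N-fragment vs WT, 395 to 583 for C-fragment vs WT, 2984 to 4682 for N+C vs WT, 3399 to 4846 for beyond the sum, and list counts of 7 to 8 for WT vs void, 9 to 12 for D361E vs void, 8 to 10 for N-fragment vs void, 5 to 7 for C-fragment vs void, 7 to 9 for N+C vs void, 6 to 7 for D361E vs WT, 7 to 8 for N-fragment vs WT, 9 to 13 for C-fragment vs WT, 10 for N+C vs WT, 5 for beyond the sum.

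Directions turned in these cases, with log2 differences for genes. With unscaled values these were ribosomal protein genes (list, adjusted p = 0.994), Gbp3 0.11, Gpnmb 0.05, Dct 0.11, Ccnd1 0.10, Jund 0.089, Cdh2 0.04, Rpl13 0.01 for WT vs void; Tank 0.062, Ier3 0.076, Prdx1 0.036, Rpl22 0.13, Rpl30 0.17 for N-fragment vs void; Socs3 -0.04, Rela -0.24 for D361E vs WT; Rela -0.15 for C-fragment vs WT; Rela -0.084 for N+C vs WT; Socs3 -0.026 for beyond the sum. With the mean of probes these were Cd44 -0.33 for WT vs void; Cd44 -0.28 for C-fragment vs void; Cdkn1a -0.006 for N+C vs WT. With the filter on all arrays these were fibroblast markers (list, adjusted p = 0.369) for N-fragment vs void; fibroblast markers (list, adjusted p = 0.433) for N-fragment vs WT. With normexp with quantile normalization these were Rela -0.004 for C-fragment vs void; Rela -0.074 for C-fragment vs WT; ribosomal protein genes (list, adjusted p = 0.717), Ldha -0.032 for N+C vs WT. With N+C without arrays 1 to 3 these were cholesterol synthesis genes (list, adjusted p = 0.606) for N+C vs void. With slide as a block these were Rela -0.001 for D361E vs WT. Without D361E replicate 2 these were Rela -0.042 for D361E vs WT. With quantile normalization these were Rela -0.066 for C-fragment vs WT; ribosomal protein genes (list, adjusted p = 0.52) for N+C vs WT. Without C-fragment replicate 1 these were Rela -0.015 for C-fragment vs WT. With 1 array left out Rela reached up to 0.066 for D361E vs WT and 0.027 for C-fragment vs WT. Rela was not called under the chosen processing in any of these comparisons, and the cause was not tested.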

Other observations

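Cyba was either well expressed or absent, and its pattern did not follow the p65 sequence carried. It stood at 1.60, 1.81, 1.89 with void, 2.61, 2.61, 2.73 with WT and 2.54, 2.40, 2.31 with the N-fragment, in log2 units relative to the array's 75th percentile. With D361E it stood at -7.06, -7.95, -7.76 and with the C-fragment at -7.66, -7.88, -7.26, and the 5 N+C arrays held both states (2.27, 2.21, 2.37, -7.72, -7.89). The gene was chosen after its values were seen, and the cause of its pattern was not tested here.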
